A study of Mus musculus with 9 samples.

How the data were processed

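RNA was measured in whole skin of unirradiated mice on the C57BL/6 background, an inbred laboratory strain. Skin came from 5 mice lacking Cd1d, the antigen-presenting molecule that shows lipids to natural killer T cells, and from 4 wild-type mice described as age and sex matched. Per the labels, each mouse was an individual sample with its own array, so the spread between arrays includes the spread between animals. The RNA was turned into biotin-labelled cRNA and hybridised to Affymetrix MG-U74 GeneChips, short-oligonucleotide arrays on which a gene is read by 1 or more probe sets. Skin after ultraviolet irradiation was not analysed here.

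The authors made the signals with Microarray Suite 5.0 (MAS5), per the labels, a program that subtracts mismatch-probe signal and gives a robust average per probe set. The deposited values are on a natural log scale, which was settled from the numbers themselves. The exponential of every value, in 100% of cases and in all 9 arrays, is a whole multiple of 0.1, to within 0.002 of that step. The mean of the resulting signals, trimmed by 2% at each end, lies between 200.11 and 200.133 in every array, so the arrays had been scaled to one target before the log was taken. The median deposited natural log value per array runs from 4.28 to 4.47. Detection calls and scanner images were not used here. MAS5 gives low signals a large relative error, and without calls the level at which a probe set is above its background is unknown. An array has no sequencing depth, so it is the number of mice that limits the precision.

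The array carries 12488 probe sets, of which 66 are AFFX control probe sets, and 1 value is missing, in the array of knockout 1. Gene symbols came from the platform annotation, in which 10833 probe sets have 1 gene, 396 have several and 1193 have no gene name here. A probe set with several genes was given no gene name. Of the 1-gene probe sets, 10817 matched the mouse gene table of assembly GRCm38.p6 through their Entrez identifier, and that table supplied chromosomes and gene order but no coordinates, because the array names no genome build.

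Deposited values were divided by the natural log of 2 to give log2 signal and were not normalised again. A pseudocount of 16 had been foreseen for linear signals, with logged values to be used as they are. The values proved to be logged, so the main setting has no pseudocount and 16 became an added alternative. Control probe sets were left out, and a probe set was kept where its signal was at or above the 40th percentile of the array in at least 4 of the 9 arrays. This level is a signal of 43.4 to 53.3, depending on the array. It left 7658 probe sets, of which 6919 have 1 gene, 262 have several and 477 have none. Log2 differences are knockout minus wild type throughout.

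Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment over the kept probe sets and a threshold of adjusted p 0.05. Each of the 32 gene lists was tested as a group with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 31 lists with at least 5 measured genes. For these lists a gene was represented by its kept probe set with the highest mean signal over all 9 arrays, which gave 5855 genes. Because camera with a small preset correlation assumes that genes of a list vary almost independently between mice, every list was also tested with a correlation estimated from the arrays, and with fry, which asks whether the genes of a list move, on balance, one way. Members of a list were in addition adjusted over the list alone. For the Cd1d probe sets an exact permutation test was run over the 126 arrangements of 5 and 4 arrays, whose smallest possible p is 0.00794. Some genes stand in 2 or 3 lists, such as Ctss and B2m, so the lists are not independent of one another.

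The comparison, the filter, the tests, the gene lists, the rule for naming genes and most alternative settings were fixed before the data were examined. The rule named the Cd1d genes and the probe sets with 1 gene that passed the threshold without overlap between the groups. It then added the genes with the smallest p until 20 were named. Up to 4 members per list with the smallest p and up to 10 measured genes on each side of Cd1d1 completed it. Genes outside the rule that appear in the text, among them the passing probe set with several genes, the other globin probe sets and the immunoglobulin probe sets, were chosen after their values were seen.

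The procedure was tested on simulated arrays with the means and spread of the 7658 real probe sets, 5 against 4 arrays, 200 probe sets changed and 20 runs. It recovered 27.2% of changes of 1.5-fold, 69.5% of changes of 2-fold and 95.1% of changes of 4-fold, and 4.49% of its calls were false. A shift of -0.50 (log2) placed on 1 list was called in 20 of 20 runs, with 1 call among all other lists. These simulated genes varied independently, so the run says nothing of lists whose genes vary together between mice. The shift was also equal in every gene of its list. No list median in the main setting was as low, the lowest being -0.41 for MHC class II, so smaller shifts were not covered.

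Pairwise correlations of log2 signal over the kept probe sets were 0.892 to 0.968 (median 0.948) for the 16 pairs within groups and 0.904 to 0.961 (median 0.931) for the 20 pairs between groups. No 2 arrays were duplicates of each other. The SD of an array's deviation from its group mean was largest for knockout 4 (0.497) and wild type 2 (0.388), against 0.273 to 0.326 for the others. The deposited values of knockout 3, 4 and 5 and wild type 1 have 9 decimals and those of the other arrays 7. This may mark separate exports or experimental batches, which the labels do not say. It crosses the groups and was tried as a block and by fitting the arrays of each kind alone. The 7-decimal arrays are 2 knockout and 3 wild-type, and the 9-decimal arrays 3 knockout and 1 wild-type. A fit of the latter rests on a single wild-type mouse, whose spread limma takes to be that of the knockout arrays, so its calls decide nothing.

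The alternatives fixed in advance were a replicate-number block, quantile normalisation, median centring, pseudocounts of 1 and 64, no filter, a filter at the 60th percentile, eBayes without trend or with robust hyperparameters, array weights, a 2-fold minimum, an ordinary two-sample test with unequal variances, each array left out in turn, an estimated list correlation, fry, and the median of a gene's probe sets. Added after seeing the data were the pseudocount of 16, the decimals as a block, fits within the arrays of each number of decimals, a fit without knockout 4 and wild type 2, the hair follicle list median per array as a covariate, and an exact permutation test of each list's median per array.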

Results

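Skin of unirradiated Cd1d knockout and wild-type mice was compared to ask how the tissue differs at baseline without CD1d, before any ultraviolet exposure. The data comprise 9 arrays, 5 from knockout and 4 from wild-type mice, each from a different animal. Signals are in arbitrary MAS5 units and are given as mean ± SD.

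The Cd1d1 transcript, which encodes the CD1d molecule, had a lower signal in the knockout skin but was not at zero. Its own probe set (Cd1d1 lies on chromosome 3) read 60.3 ± 12.7 in the knockout mice (SD, n = 5) and 109 ± 16.7 in the wild-type mice (SD, n = 4). The 5 knockout values (58.2, 65, 79.6, 47.6 and 51.1 for knockout 1 to 5) all lay below the 4 wild-type values (112.4, 101.1, 91 and 130 for wild type 1 to 4). The log2 difference was -0.86 (SE 0.20, 95% interval -1.29 to -0.43), which leaves 55.1% of the wild-type level on this scale, and at pseudocount 64 it was -0.47. The exact two-sided permutation test gave p = 0.0159, while limma gave p = 0.000978 and an adjusted p = 0.242 over all probe sets, so the gene did not pass the threshold among 7658 tests. The knockout level is close to the signal used as the filter, and whether the probes lie inside the deleted part of the gene is unknown, so the residual signal says nothing about intact transcript. A probe set shared by Cd1d1 and its close copy Cd1d2 read 261 ± 41.9 in knockout and 348 ± 46.6 in wild-type skin, a log2 difference of -0.42 (limma adjusted p = 0.442). The probe set of Cd1d2 alone was too dim to be kept, at 17.3 ± 5.28 and 8.88 ± 2.97.

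Few single genes passed the threshold. In knockout skin the red-cell globin transcripts fell, with Hba-a1 (alpha globin) at 1263 ± 237 against 3292 ± 612 and Hbb-b2 (beta globin) at 224 ± 41.7 against 592 ± 118. These are differences of 2.61-fold and 2.64-fold, and each knockout mouse lay below each wild-type mouse. One probe set of Ighm, the heavy chain of immunoglobulin M, rose from 16.5 ± 2.82 to 84.6 ± 20.9, and a probe set annotated to several genes rose from 37.7 ± 10.2 to 196 ± 41.5. The wild-type levels of these last probe sets lie below the filter signal, so their folds of 5.08 and 5.28 are uncertain.

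These 4 probe sets, 2 higher and 2 lower in the knockout, are all that passed limma's threshold of adjusted p 0.05 among 7658. The limma log2 differences and adjusted p values were -1.38 (SE 0.16) and 0.00531 for Hba-a1, -1.40 (SE 0.18) and 0.00896 for Hbb-b2, 2.34 (SE 0.27) and 0.00531 for Ighm, and 2.40 (SE 0.24) and 0.00358 for the probe set with several genes. At an unadjusted p under 0.05 limma called 720 probe sets, 417 higher and 303 lower, where 382.9 would be found by chance. The groups did not overlap for 246 probe sets (3.21%, against 1.59% by chance). The ordinary two-sample test with unequal variances called 0 probe sets after adjustment, with 581 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0572. The count of 4 became 7 without knockout 2 or without knockout 3 and 8 without knockout 4, with these 4 among them each time. With the hair follicle list median of each array as a covariate, Hbb-b2 did not pass (limma adjusted p = 0.0623), although its log2 difference of -1.31 (SE 0.20) was about as large as the -1.40 (SE 0.18) without it. Its SE was larger and 1 residual degree of freedom fewer was left. Deposited values have 7 decimals in some arrays and 9 in the others, which may mark exports or experimental batches. Within the 7-decimal arrays, 2 knockout against 3 wild-type arrays, 10 probe sets passed limma's threshold. Among them were Hba-a1 (log2 -1.62, adjusted p = 0.0300) and Hbb-b2 (-1.74, 0.0300) but not Ighm (2.24, 0.190) or the probe set with several genes. The 9-decimal arrays have only 1 wild-type mouse, too few for a call. There the log2 values were -1.02 for Hba-a1, -0.92 for Hbb-b2 and 2.41 for Ighm.

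The globin result rested on several probe sets. All 5 kept haemoglobin probe sets had lower values in the knockout, from -1.40 to -0.18 (log2). Near-identical copies of these genes share probe sequence, however, and cannot be separated with certainty. The smallest difference, -0.18, was that of Hba-ps3, at 195 ± 36.7 against 220 ± 34.9 with overlapping groups (limma adjusted p = 0.788). A probe set shared by several beta globin genes read 1533 ± 508 against 3788 ± 597 (log2 -1.35, limma adjusted p = 0.0540). A probe set shared by the alpha globins Hba-a1 and Hba-a2 read 560 ± 143 against 1048 ± 148 (log2 -0.94, limma adjusted p = 0.210). The immunoglobulin result did not. The 3 other kept probe sets of Ighm had log2 differences of -0.43, -0.13 and -0.04, opposite in sign to the one that rose, with limma adjusted p values of 0.575, 0.920 and 0.967.

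**Figure D1:**
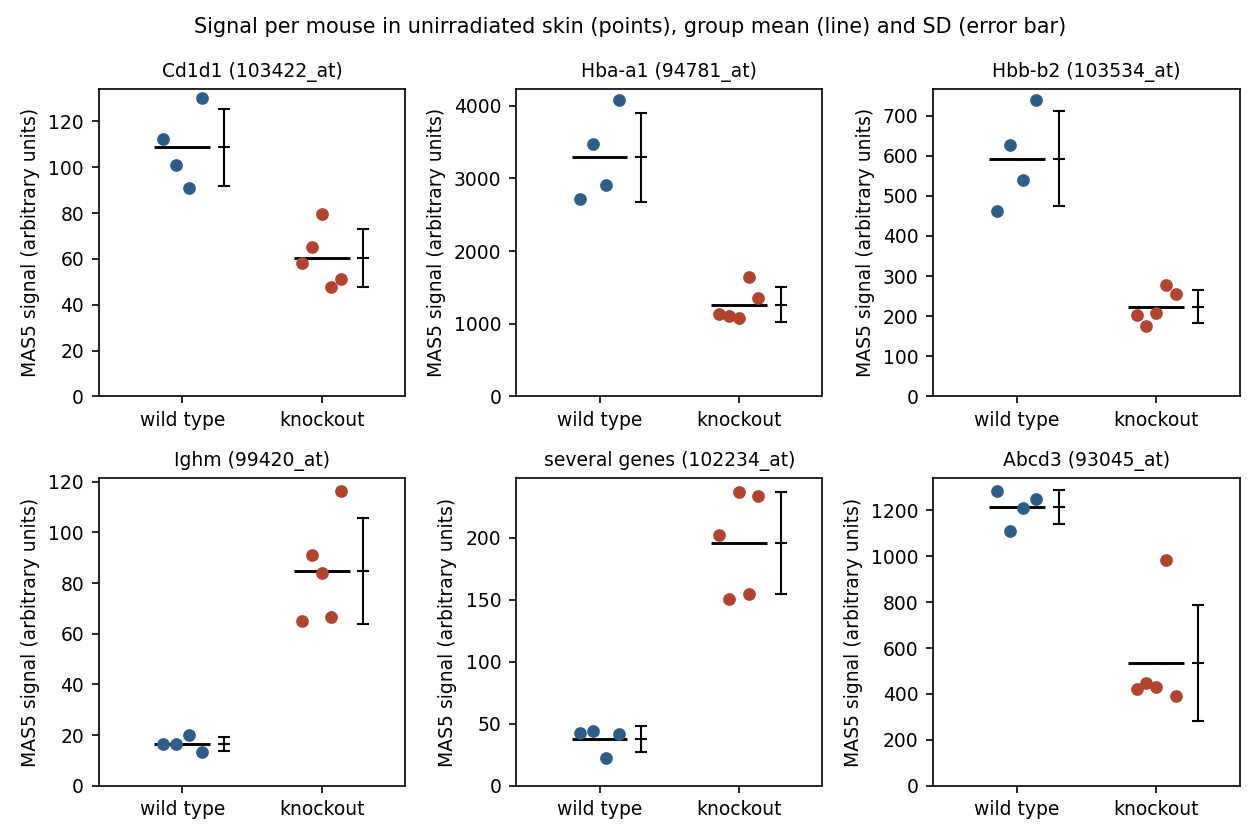
MAS5 signal (arbitrary units, vertical axes from 0) of 6 probe sets in each of the 4 wild-type and 5 knockout mice, with the group mean as a line and the SD as an error bar. The groups do not overlap in any of the 6, and knockout 4 has an Abcd3 signal of 984.9 where the other knockout mice lie between 390.1 and 446.8.

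A further 17 genes with the smallest p values did not pass and are given as values. Adh7, an alcohol dehydrogenase that also oxidises retinol, came closest, at 777 ± 71.0 in knockout and 1404 ± 232 in wild-type skin (log2 -0.84, limma adjusted p = 0.0540). It passed in 6 of its 25 alternatives, among them 1 of the 9 with 1 array left out, where the limma adjusted p ran from 0.0284 (without wild type 2) to 0.281. Abcd3, a peroxisomal membrane transporter, read 535 ± 252 against 1215 ± 75.0 (log2 -1.28, limma adjusted p = 0.145). Its knockout mean rests on 4 low values and 1 high value from knockout 4, and without that array its limma adjusted p was 0.000138. Other lower signals were those of Mob2 (log2 -2.003, and -0.73 at pseudocount 64, its knockout mean of 19.2 lying below the filter signal), Syngr2 (-0.61), Tmem176a (-0.61), Tpsb2, a mast cell tryptase (-0.60), and Msrb1, a methionine sulfoxide reductase (-0.49).

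Among the higher signals, several belong to genes of RNA processing and translation. The splicing factor Srsf1 read 128 ± 8.97 against 78.4 ± 9.46 (log2 0.72), Hnrnpa2b1, an RNA-binding protein, 1210 ± 85.3 against 831 ± 110 (0.55), and Dicer1, the nuclease that matures microRNAs, 86.3 ± 15.4 against 41.9 ± 9.73 (1.06). The translation termination factors Gspt1 and Etf1 had log2 differences of 0.64 and 0.70. Their limma adjusted p values lay between 0.168 and 0.204, and no list of these functions had been fixed, so the theme itself was not tested. The second kept probe set of Srsf1 gave 0.73 and that of Hnrnpa2b1 0.56, whereas the 3 other probe sets of Etf1 gave 0.23, 0.14 and 0.03. The remaining higher values were those of Dnase1l3 (1.86), Sgip1 (1.41), Trim59 (1.06), Isoc1 (0.62) and Lep, the adipocyte hormone leptin (1.88, with 0.41 at its other probe set). The wild-type means of Dnase1l3 (23.9), Lep (36.7) and Dicer1 lie below the filter signal, so their folds are uncertain too. At pseudocount 64 the log2 differences were 0.70 for Dnase1l3, which passed there (limma adjusted p = 0.0446), 1.04 for Lep, 0.50 for Dicer1, 0.85 for Sgip1, 0.58 for Trim59 and 0.44 for Srsf1. The limma adjusted p of Lep was 0.235, and 0.00432 without knockout 2, whose signal of 41.6 was close to the wild-type mean. That of Trim59 was 0.172, and 0.0471 without knockout 3.

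As groups, genes of antigen presentation and of macrophages and dendritic cells were lower in knockout skin, by small amounts. All 22 measured macrophage and dendritic cell markers had lower values, with a median log2 of -0.29 (camera in limma, adjusted p = 1.72e-07, and adjusted p = 0.139 with an estimated correlation). Csf1r, the receptor for the macrophage growth factor, read 1006 ± 110 against 1342 ± 154 (log2 -0.41), C1qa of the complement C1q complex 1772 ± 300 against 2279 ± 197 (-0.38), Laptm5, a lysosomal protein of white blood cells, 1047 ± 143 against 1344 ± 122 (-0.37) and lysozyme Lyz2 1849 ± 267 against 2323 ± 243 (-0.34). Of these 22 genes 0 passed limma's test over all genes. Adjusted over the list alone 0 passed, with a smallest adjusted p of 0.0949, while 8 had an unadjusted p under 0.05. The list medians per array were -0.16, -0.24, -0.07, 0.02 and -0.01 in knockout 1 to 5, all below the wild-type range (0.05 to 0.21). The exact permutation test of these medians gave p = 0.0159, and 0.246 after adjustment over the lists.

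The 10 measured genes of the MHC class II pathway, which presents peptides to helper T cells, were all lower, with a median of -0.41 (camera adjusted p = 1.30e-06, and adjusted p = 0.406 with an estimated correlation). Adjusted over the list alone, H2-Eb1, the protease Ctss and H2-DMa passed limma's test, and 0 passed over all genes. H2-Eb1 fell from 3689 ± 337 to 2563 ± 533 (log2 -0.54, adjusted p over the list alone 0.0145), Ctss from 1901 ± 225 to 1333 ± 220 (-0.52, 0.0145), and H2-DMa from 1213 ± 135 to 896 ± 138 (-0.44, 0.0223) by that limma test. H2-Aa read 3520 ± 833 against 4557 ± 552 (-0.40). The list medians per array were -0.38, -0.43, 0.21, -0.12 and -0.15 in knockout 1 to 5, so that of knockout 3 lies inside the wild-type range (0.05 to 0.40). With the hair follicle median of each array as a covariate the list median was -0.22 (camera adjusted p = 0.000830).

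In the list for lipid antigen presentation by CD1d, 9 of 12 genes were lower, with a median of -0.18 (camera adjusted p = 0.000493, and adjusted p = 0.139 with an estimated correlation). This list includes the targeted gene. Adjusted over the list alone 3 genes passed limma's test, Cd1d1 itself (adjusted p 0.0117), Ctss (0.0174) and B2m, the light chain of CD1d and of MHC class I (0.0332), against 0 over all genes. B2m read 3791 ± 493 in knockout and 4805 ± 315 in wild-type skin (log2 -0.35). The lysosomal enzyme Hexa had a log2 difference of -0.39. Of the 13 genes of MHC class I and its peptide supply 12 were lower, with a median of -0.16 (camera adjusted p = 0.000493, and adjusted p = 0.498 with an estimated correlation). H2-M3 passed limma's test adjusted over the list alone (239 ± 34.3 against 345 ± 35.7, log2 -0.54, adjusted p 0.0332), and 0 genes passed over all genes. The median of the class I list was -0.24 without knockout 3, -0.27 without knockout 4 and -0.24 without wild type 4, but -0.11 without knockout 2. With the hair follicle median of each array as a covariate it was -0.06 and the list was not called (camera adjusted p = 0.237). Within the 7-decimal arrays, with knockout 1 and 2 as their only knockout mice, it was -0.41 (camera adjusted p = 1.14e-07). Within the 9-decimal arrays with their 1 wild-type mouse it was 0.05. Per array, the class I medians of knockout 3 (0.26) and knockout 4 (0.07) lay inside the wild-type range (0.04 to 0.27).

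Interferon-response genes were lower in 17 of 21 cases, with a median of -0.18 (camera adjusted p = 0.00909, and adjusted p = 0.606 with an estimated correlation). Irf8 (log2 -0.37) and Isg15 (-0.40) are examples. The interferon list medians per array were -0.20, -0.47, 0.23, 0.15 and -0.02 in knockout 1 to 5. Those of knockout 3, 4 and 5 lie inside the wild-type range (-0.07 to 0.36), so the lowering was not common to the knockout mice. Inflammatory cytokines and chemokines were lower in 15 of 21 cases, with a median of -0.13 (camera adjusted p = 0.0486, and adjusted p = 0.498 with an estimated correlation). The chemokine Ccl9 read 1059 ± 480 against 1963 ± 378 (-0.97) and the eosinophil attractant Ccl11 140 ± 40.2 against 211 ± 55.4 (-0.60). In both lists 0 genes passed limma's test over all genes and 0 adjusted over the list alone. The interferon call was lost without knockout 1 (camera adjusted p = 0.0600), knockout 2 (0.245, median -0.10), wild type 1 (0.0984) or wild type 2 (0.0988), and with the filter at the 60th percentile (0.171). With the hair follicle median of each array as a covariate it was lost too (camera adjusted p = 0.918, median -0.08). The cytokine call was lost without knockout 1 (camera adjusted p = 0.168), knockout 2 (0.173, median -0.08), knockout 4 (0.118), wild type 1 (0.0751) or wild type 2 (0.0988), and without wild type 4 its median was -0.05 (0.0416). It was lost as well with median centring (camera adjusted p = 0.0604), pseudocount 16 (0.0515) or 64 (0.0539, median -0.07), no trend (0.0539), array weights (0.124) and the median of a gene's probe sets (0.0539), and without knockout 4 and wild type 2 (0.206). The hair follicle covariate removed the cytokine call too (camera adjusted p = 0.159). The cytokine list passed in 12 of its 29 alternatives and the interferon list in 19 of 29.

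Hair follicle genes gave the largest list median, 1.51, with 23 of 25 genes higher in the knockout (camera adjusted p = 2.27e-08, and adjusted p = 0.498 with an estimated correlation). The difference came with a very wide spread among the knockout mice. Krt25, a keratin of the inner root sheath, read 2648, 4916, 52.1, 4.6 and 2893 in knockout 1 to 5 and 13.4, 3.8, 148.3 and 3 in wild type 1 to 4. The hair shaft keratin Krt35 read 466 ± 457 against 67.8 ± 12.8 (log2 1.91), Dlx3, a transcription factor of the follicle, 438 ± 300 against 157 ± 16.5 (1.14) and Krt36 248 ± 110 against 113 ± 13.7 (1.02). The list median per array, centred on the mean of the 9 arrays, was 0.64, 2.70, -0.76, -1.69 and 2.52 in knockout 1 to 5, and -0.87, -1.35, 0.05 and -0.78 in wild type 1 to 4. The exact permutation test of these medians gave p = 0.230. Of the 25 genes 0 passed limma's test over all genes and 0 adjusted over the list alone, and the median difference was 0.99 without knockout 2 and 0.99 without knockout 5.

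Cell-cycle genes were higher in 34 of 36 cases, with a median of 0.44 (camera adjusted p = 1.72e-07, and adjusted p = 0.530 with an estimated correlation). The list medians per array were 0.70, 0.51, -0.25, 0.03 and -0.000920 in knockout 1 to 5, against -0.57 to 0.157 in the wild-type mice, so only knockout 1 and 2, which are among the 3 arrays with the highest hair follicle medians, lie above the wild-type range. The exact permutation test of these medians gave p = 0.143. With the hair follicle median as a covariate the list median was 0.28 (camera adjusted p = 0.00131). Mki67, a marker of cycling cells, read 152 ± 69.8 against 68.8 ± 31.9 (log2 1.11), the ribonucleotide reductase Rrm1 220 ± 57.3 against 119 ± 69.9 (1.06), Birc5, which acts in cell division, 80.6 ± 35.3 against 41.5 ± 12.6 (0.92) and cyclin Ccna2 253 ± 61.7 against 169 ± 34.0 (0.57). Of the 36 genes 0 passed limma's test over all genes and 0 adjusted over the list alone, and without knockout 1 the median was 0.29. Within the 7-decimal arrays, whose only knockout mice are these same knockout 1 and 2, the median was 1.08 (camera adjusted p = 2.95e-25). Within the 9-decimal arrays it was -0.31, but there it rests on 1 wild-type mouse, wild type 1, which has the highest median of its group, so the direction is not settled for these arrays. Genes of the sebaceous gland and of lipid synthesis were higher in 21 of 26 cases, with a median of 0.27 (camera adjusted p = 0.000416, and adjusted p = 0.498 with an estimated correlation). Here Hmgcs1, an early enzyme of cholesterol synthesis, passed limma's test adjusted over the list alone (808 ± 150 against 502 ± 74.7, log2 0.68, adjusted p 0.0239), and 0 genes passed over all genes. Idi1 (0.69), Sc5d (0.73) and Nsdhl (0.47), all of the same pathway, had values in the same direction, and the list median was 0.16 without wild type 3.

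Skeletal muscle transcripts, from the thin muscle layer under mouse skin, were lower in 31 of 37 cases, with a median of -0.21 (camera adjusted p = 2.55e-05, and adjusted p = 0.515 with an estimated correlation). The calcium channel genes Cacng1 and Cacna1s had log2 differences of -0.45 and -0.42 and tropomyosin Tpm2 -0.39, while Tpm1 had 0.49. Of the 37 genes 0 passed limma's test over all genes and 0 adjusted over the list alone, and without wild type 2 the list was not called (median -0.10, camera adjusted p = 0.148). The list for blood was lower by camera, with a median of -0.23 over 7 genes (adjusted p = 0.00357, and adjusted p = 0.406 with an estimated correlation). Hba-a1 and Hbb-b2 passed limma's test over all genes, and adjusted over the list alone Alas2, the red-cell enzyme of haem synthesis, passed as well (71.3 ± 25.9 against 140 ± 43.7, log2 -1.004, adjusted p 0.0123). Car2 (0.35), Bpgm (0.13) and Klf1 (0.47) had higher values. With only 7 genes the blood median moved widely, to -0.35 without knockout 1, -0.44 without knockout 2, -0.01 without knockout 3, 0.00412 without knockout 4, -0.34 without knockout 5, -0.42 without wild type 2 and -0.12 without wild type 3. It was -0.08 at pseudocount 64 and -0.14 without a filter. It was not called with array weights (camera adjusted p = 0.0585) or without both knockout 4 and wild type 2 (0.139).

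**Figure D2:**
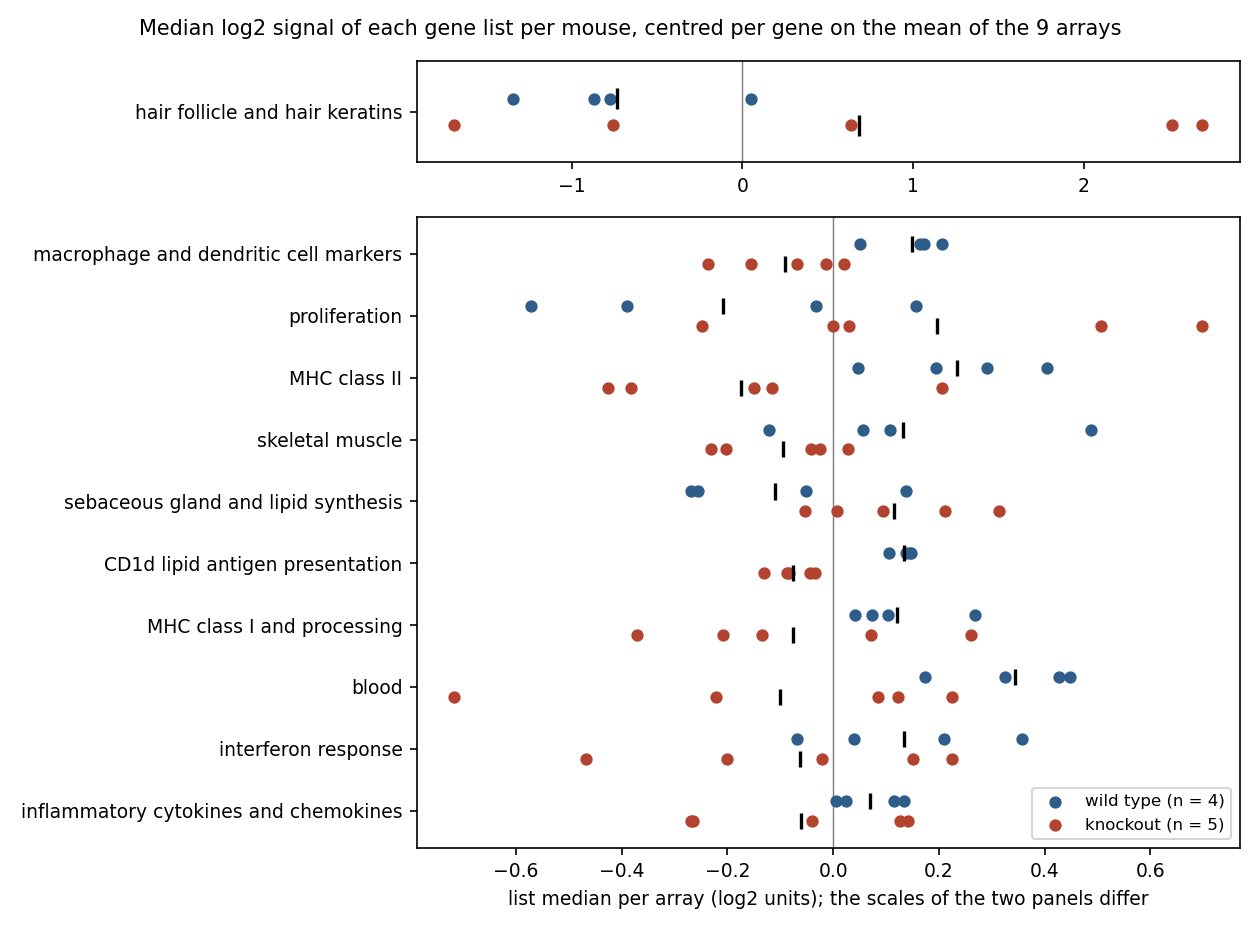
Median log2 signal of each of the 11 gene lists past camera's threshold, per mouse, after each gene was centred on its mean over the 9 arrays (points, with the group mean as a black tick; the upper and lower panels have different horizontal scales). For the lipid antigen presentation list, which includes the targeted Cd1d1, all 5 knockout mice lie below all 4 wild-type mice. The same holds for macrophage and dendritic cell markers. The hair follicle medians of the knockout mice run from -1.69 to 2.70.

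In all, camera called 11 of 31 lists, 3 higher and 8 lower. With an estimated correlation 0 lists passed (smallest adjusted p = 0.139, with 3 lists at an unadjusted p under 0.05). By fry 2 passed, lipid antigen presentation by CD1d (adjusted p = 0.00584) and macrophage and dendritic cell markers (adjusted p = 0.0311). The lipid antigen presentation list holds the targeted Cd1d1 itself, and it was not tested without that gene. In the exact permutation test of the list medians 0 passed after adjustment and 4 had an unadjusted p under 0.05. With a smallest possible p of 0.00794 over 31 lists, at least 5 lists would have to reach it for any to pass, so this test could hardly pass a list. Lipid antigen presentation was at that smallest p. With the hair follicle median of each array as a covariate, blood (median -0.80, camera adjusted p = 0.000238) and the sebaceous list (0.40, 2.31e-06) were still called, as were MHC class II, proliferation, macrophages, lipid antigen presentation and muscle, while MHC class I (-0.06, 0.237), the interferon response (-0.08, 0.918), the cytokines (-0.12, 0.159) and the hair list itself (0.28, 0.216), which this covariate removes by construction, were not. With the number of decimals of the deposited values as a block, 12 lists were called, among them the same 11, and the same 4 probe sets passed. The blood list was among those called, but its median there was 0.000588. Within the 7-decimal arrays camera called 14 lists, among them 10 of the 11, and blood was not called (median 0.21, camera adjusted p = 0.0529). The only knockout mice in that fit are knockout 1 and 2. Of the knockout mice these had the lowest medians for MHC class I and II, the interferon response and cytokines, and the highest for proliferation. Its calls therefore do not speak for the other knockout mice. Within the 9-decimal arrays no call is drawn, and the blood median was -0.64. In the 7-decimal and the 9-decimal arrays the medians were -0.34 and -0.22 for macrophage and dendritic cell markers, -0.55 and -0.24 for MHC class II, -0.19 and -0.22 for lipid antigen presentation, -0.41 and -0.20 for the interferon response and -0.36 and -0.10 for cytokines. They were 2.29 and 0.78 for hair follicles, 0.23 and 0.04 for the sebaceous list and -0.32 and -0.17 for muscle.

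The lists closest to the study's interest in cell survival after ultraviolet light did not pass in this unirradiated skin. The median log2 was -0.07 for 26 targets of the tumour suppressor p53 (camera adjusted p = 0.143), 0.10 for 27 nucleotide excision repair genes (0.257), -0.08 for 25 pro-apoptotic genes (0.477) and -0.05 for 26 anti-apoptotic genes (0.490). With 1 array left out the median ran from 0.0414 to 0.112 for excision repair, from -0.103 to -0.0377 for pro-apoptotic and from -0.109 to 0.0148 for anti-apoptotic genes, and 0 of these 3 lists were called. The p53 median ran likewise from -0.16 to 0.00783, and that list was called lower in 4 of its 29 alternatives: without wild type 1 (-0.13, camera adjusted p = 0.0386), with array weights (-0.11, 0.0281), without knockout 4 and wild type 2 (-0.10, 0.0496) and within the 7-decimal arrays (-0.16, 0.0193). In each of these 4 lists 0 genes passed limma's test over all genes and 0 adjusted over the list alone. Rela, a subunit of NF-kappaB, read 1158 ± 199 against 1559 ± 59.2 (log2 -0.44, adjusted over the list alone 0.112 by limma). The 8 measured markers of T, NK and NKT cells, of which CD1d shows lipids to the NKT cells, had a median of 0.00 (camera adjusted p = 0.662). The list does not measure NKT cells by themselves. Cd4 read 101 ± 30.3 against 106 ± 25.1 and Cd3g 44.6 ± 15.0 against 42.6 ± 16.2, both at low signal.

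Other lists that did not pass were those of melanocytes (median 0.47, camera adjusted p = 0.0772), endothelium and vascular smooth muscle (-0.08, 0.179), immediate early and heat shock genes (0.10, 0.213), oxidative phosphorylation (-0.06, 0.2202) and antioxidant and xenobiotic defence (-0.08, 0.2202). Dermal fibroblasts and matrix (0.07, camera adjusted p = 0.373), adipocytes (0.12, 0.393), the circadian clock (0.04, 0.406), neutrophils (0.18, 0.435), B cells and immunoglobulin (-0.09, 0.477), nerve and Schwann cells (-0.13, 0.484), cytosolic ribosomal proteins (-0.03, 0.490), mast cells (-0.005, 0.576), the cornified envelope (-0.05, 0.711) and basal keratinocytes (0.02, 0.711) did not pass either. Some of these calls depended on the setting. The melanocyte list was called higher in 7 of its 28 alternatives, with the smallest adjusted p within the 7-decimal arrays (median 0.66, camera adjusted p = 3.14e-06) and without a filter (0.65, 0.000275). Oxidative phosphorylation was called without wild type 2 (0.0896, the other direction, camera adjusted p = 0.0362), wild type 3 (-0.08, 0.0184) or wild type 4 (-0.13, 0.000293). Calls were also gained by adipocytes and by dermal fibroblasts in 3 of 29 alternatives each and by endothelium, as lower, in 2. Immediate early and heat shock genes had a median of 0.26 within the 9-decimal arrays, whose single wild-type mouse is too few for a call. The medians of mast cells, B cells, T, NK and NKT cells, basal keratinocytes, the cornified envelope, ribosomal proteins, dermal fibroblasts and the circadian clock changed sign when some single array was left out, without a call in the other direction. Median and test differ in sign for the cornified envelope, whose test leaned higher, and for basal keratinocytes and T, NK and NKT cells, whose tests leaned lower. In these 15 lists 0 genes passed limma's test over all genes, and adjusted over the list alone 1 did, the mast cell tryptase Tpsb2, which fell from 622 ± 70.5 to 411 ± 49.5 (adjusted p 0.00504). Its other kept probe set read 113 ± 20.6 and 99.5 ± 10.3 (log2 -0.17, limma adjusted p = 0.792 over all genes). The list of sex-linked genes was too small to test. Its X-linked member Xist, expressed in female cells, read 290 ± 62.2 and 219 ± 84.8, and probe sets of the Y-linked genes Kdm5d, Eif2s3y, Uty and Sry lay below the filter.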

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

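The tests of the hair follicle and haemoglobin patterns below were chosen after the results were seen, while the search for outlying mice and the counts over other splits of the arrays were planned. Of 108 groups of 4 or 5 values examined, 5 had a sample far from the rest, and chance flags about 1 in 20 groups, or 5.4 here, so these values are no excess. Abcd3 read 984.9 in knockout 4 and 390.1 to 446.8 in the other knockout mice. Sgip1 read 277.7 in knockout 4 and 148.7 to 162.3 in the others. Mob2 read 34.5 in knockout 1 and 13.1 to 19 in the others. Lep, at the probe set with the smaller p, read 34 in wild type 1 and 37.4 to 37.7 in the other wild-type mice, a small gap in a very tight group. The median of the cornified envelope list was 0.155 in wild type 1 and -0.02 to -0.01 in the others.

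Other splits of the 9 arrays into 5 and 4 were drawn 100 times, the real one included. Of these, 2 gave as many as 4 probe sets past the threshold, the real split with 4 and another with 4. That share lies below 0.05, but only 100 of the 126 possible splits were drawn. The ordinary two-sample test with unequal variances called 0 probe sets in the real split. Chance is thus made less likely for this count, but it is not excluded. The other split sets knockout 3 and 4 and wild type 1, 2 and 4 against the rest, which are the 4 arrays with the highest hair follicle medians. For the gene lists, 10 of the 100 splits gave 11 lists or more, with 12 the highest of the others and 11 in the real split, so chance is not excluded for the number of lists called by camera. One of the 4 splits with 12 lists sets knockout 3, 4 and 5 and wild type 1, the arrays with 9 decimals, together with wild type 2 against the rest, and with the decimals as a block the real comparison still called 12 lists. Within the 7-decimal arrays, whose only knockout mice are knockout 1 and 2, it called 14, and the 9-decimal arrays hold too few wild-type mice (1) for a call.

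The higher hair follicle values were not a shift in every knockout mouse, since 3 of the 5 lay above the highest wild-type mouse and knockout 4 had the lowest median of all 9 arrays (-1.69). Mice at different stages of hair growth are a candidate explanation, because growing follicles make pigment as well as keratin. The 3 arrays with the highest hair follicle medians (knockout 2, 5 and 1) were also the 3 with the highest melanocyte medians (0.61, 0.10 and 0.50), an overlap of 3 that chance gives with p = 0.0119 by exact counting over the arrays, and no gene is in both lists. That count treats all 9 arrays alike, and its cut at 3 was chosen with the values known. The shared arrays are all knockouts and both lists leaned higher in the knockout, so the overlap cannot tell hair stage from genotype. Whether Cd1d loss itself alters hair growth was not tested and stays open, since the stage of the hair cycle was not among the labels used here.

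The lower haemoglobin transcripts may reflect less blood in the knockout samples, which the values leave open. Alas2, which red-cell precursors express with the globins, had a log2 difference of -1.004, and its 95% interval holds the change of Hba-a1. Other genes of the blood list did not follow it, with higher values that did not pass for Klf1 (0.47), Car2 (0.35) and Bpgm (0.13). Which cells of the skin their signal came from was not tested. A strain variant in the beta globin genes does not account for the pattern by itself, because the alpha globin Hba-a1, on another chromosome, also fell (log2 -1.38, 95% interval -1.73 to -1.03). Fewer vessels do not account for it by themselves, because the 23 genes of endothelium and vascular smooth muscle had a median log2 of -0.0774 (SD of the members 0.27, lowest -0.55), far above the globin change. That list was called lower without knockout 4 (median -0.15, camera adjusted p = 0.0304) and within the 7-decimal arrays (-0.28, 0.00287). These medians are still far above the globin change. Bleeding at dissection and fewer reticulocytes were not separated.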

How the results depend on the processing

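The alternatives named as added in the methods (pseudocount 16, the decimals block, the fits within the arrays of each number of decimals, the fit without knockout 4 and wild type 2, the hair covariate, the exact test of list medians) were chosen after seeing the data. Over single genes, 474 gene and setting pairs kept direction and side of the threshold, 7 lost the call, 13 gained it and 0 reversed. Over lists the numbers were 802, 64, 22 and 6, and a sign change with no call on either side counts as unchanged. Of those 64 lost calls 11 come from the exact permutation test of medians, which could hardly pass a list after adjustment. Most of these lists were above 0.05 in that test before adjustment too. The estimated correlation, fixed in advance, also lost all 11 list calls, and fry kept only 2 of them. Most of the 474 unchanged gene pairs belong to named genes that did not pass in the main fit and stayed so. Likewise, most of the 802 unchanged list pairs belong to lists that were not called in the main fit. The ordinary two-sample test with unequal variances, which called 0 probe sets, is not among the gene pairs. Cd1d1 ran from -0.97 to -0.47 (log2) and never passed limma's threshold, and a filter at the 60th percentile left it out. Hba-a1 passed in 24 of its 25 alternatives in limma and Ighm in 21 of 24, and the log2 of Ighm, 2.34, became 0.87 at pseudocount 64 and 1.55 with quantile normalisation. Low signal over background limits the size of such folds.

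The count of 4 probe sets became 7 at pseudocount 64, 9 with array weights, 10 without knockout 4 and wild type 2, 0 with unequal variances, and 10 and 0 within the 7-decimal and 9-decimal arrays, and ran from 4 to 8 with 1 array left out. The count of 11 lists became 0 with an estimated correlation, 2 by fry, 0 by that exact permutation test and 2 within the 9-decimal arrays, which hold 1 wild-type mouse and decide nothing, and ran from 9 to 12 with 1 array left out. The blood median turned to 0.00412 without knockout 4, 0.000588 with the decimals block and 0.209 within the 7-decimal arrays, and that of oxidative phosphorylation to 0.0896 without wild type 2. Within the 9-decimal arrays the median of proliferation turned to -0.31 and that of MHC class I to 0.0462. With 1 array left out the blood median ran from -0.437 to 0.00412 and that of oxidative phosphorylation from -0.13 to 0.0896. The cause was not tested, beyond the fewer arrays.

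Replicate numbers gave no sign of pairing the mice, although so few correlations cannot exclude it. Deviations of same-numbered arrays correlated at 0.106, -0.012, -0.046 and 0.019. With the replicate block, 1 probe set passed, 11 lists were called and Cd1d1 was at -0.81. Hba-a1 was the one that passed. Hbb-b2 (limma adjusted p = 0.0584) and Ighm (0.114) did not, with log2 differences of -1.45 (SE 0.16) and 2.22 (SE 0.29) that stayed about as large. The probe set with several genes was not called either. The block left 3 residual degrees of freedom in place of 7.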

Other observations

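The immunoglobulin counts and the Fisher tests in this part were chosen after the results were seen, while the limma values come from the planned fit and the 10 genes on each side of Cd1d1 from the naming rule. Most kept probe sets of immunoglobulin kappa light chains had lower values, unlike the single Ighm probe set that rose, 15 of 17 lower and 2 higher, with 10 of the 15 at an unadjusted p under 0.05 and 0 past the threshold. Of all 28 kept immunoglobulin probe sets, heavy chains included, 24 had lower values in knockout skin and 4 higher, and 12 had an unadjusted p under 0.05, 10 of them lower. The lowest matches several kappa light chain genes and read 68.8 ± 17.8 against 181 ± 59.0 (log2 -1.38, limma adjusted p = 0.113). Igkv4-70 read 71.9 ± 24.5 against 164 ± 53.6 (-1.22) and Igkv6-23 536 ± 182 against 1148 ± 495 (-1.08). Igha, the heavy chain of immunoglobulin A, had a higher value, 178 ± 42.6 against 111 ± 36.5 (0.69), and Jchain, which joins immunoglobulin M and A into polymers, a lower one (-0.51). These probe sets share sequence, so they are not independent measurements, and only the Ighm probe set that rose passed the threshold.

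Genes on chromosome 3, which carries Cd1d1, stood out among those with the smallest p. Of 303 measured genes there, 9 (2.97%) had a limma p under 0.005, against 54 of 5547 (0.973%) elsewhere, with Fisher's exact p = 0.00476 and 0.0952 after adjustment over 20 chromosomes, so chance is not excluded. One of the 9 is Cd1d1 itself, and without it 8 of 302 genes (2.65%) gave Fisher's exact p = 0.0137 and 0.273 after adjustment. The limit of 0.005 was picked with the top genes known. At 0.001 the adjusted exact p was 0.295 and at 0.05 it was 0.337. A segment of another strain carried along with the targeted gene may contribute, yet among the 20 measured genes nearest to Cd1d1 in the gene order of GRCm38.p6, 3 (15%) had a limma p under 0.05, against 8.53% of the rest (Fisher's exact p = 0.241), which decides nothing. The 3 were Sfrp2 (log2 0.82), Glrb (0.76) and Sh3d19 (0.46). The genes with the smallest p on the chromosome, Adh7 and Abcd3, lie 184 and 159 measured genes away. Trim59 (1.06) and Selenot (0.60), with a limma p under 0.005, lie 15 and 30 away. Ctss (-0.52), which passed within the MHC class II and lipid antigen lists alone, is also among the 9 and lies 98 away.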
